A study of Homo sapiens with 25 samples.

How the data were processed

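RNA was sequenced from PC3 cells, an established human prostate cancer line that lacks androgen dependence. Per the labels' protocols, cells were grown in medium with 10% fetal bovine serum and serum-starved for 24 h. They then received epidermal growth factor (EGF) at 10 ng/mL, with or without the peptide LA3IK at 80 µM, in medium with 0.1% serum. RNA was taken at 0 h, 30 min, 1 h and 6 h. RNA was extracted with TRIzol, libraries were made with an Illumina kit for stranded mRNA, and paired reads of 75 bp came from an Illumina NextSeq, per the labels' protocols and the series design text. The labels place 24 libraries in 8 groups of 3 biological replicates and 1 library in a group of its own that received LA3IK without EGF for 6 h. Neither preparation batches nor dates were given in the sources used here.

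The deposited table holds estimated counts per gene, which the authors left unscaled for library size. The table has 58288 genes named by Ensembl identifiers and 25 columns, 1 per library, with no pooling. Reads were aligned to hg38 with HISAT2 and quantified with StringTie, per the submitters' processing notes. The processing notes name Trim Galore for read trimming and the series design text names Fastp, so the trimming tool differs between the 2 sources. The same design text names DESeq2 for the authors' own tests. Tool versions, the gene annotation and whether counting used strand were not given in the sources used here. Genes at overlapping loci can trade counts under such estimation, and antisense partners may not have been separated, so genes that overlap others or have near-identical copies are named as uncertain. Whole numbers were deposited, so no rounding was needed.

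Of the identifiers, 57577 matched GENCODE release 44 once version suffixes were removed, which supplied symbols, positions on hg38, transcript length and GC content. No line of the table lacked a gene name, and no column was left unmapped to a library. Totals ran from 13.8 to 41.4 M counts per library. The shallowest was replicate 3 of EGF at 30 min and the deepest replicate 3 of EGF at 1 h. Mean totals ± SD (n = 3) were 23.6 ± 2.37 M for EGF 0 h, 17.6 ± 3.64 for EGF 30 min, 29.0 ± 10.7 for EGF 1 h and 24.4 ± 1.32 for EGF 6 h. With both agents they were 23.0 ± 1.88 M at 0 h, 21.6 ± 0.654 at 30 min, 24.3 ± 1.10 at 1 h and 26.2 ± 2.70 at 6 h. The library with LA3IK alone held 26.2 M. No pair of replicates in a group was identical within sampling noise, since the chi-square statistic per degree of freedom over genes was between 2.99 and 24.5.

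Tests used edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. All 24 libraries of the replicated groups entered 1 quasi-likelihood fit (robust) with 1 coefficient per group, TMM scaling and edgeR's filter on low counts, which kept 18397 genes. P-values were adjusted by the Benjamini-Hochberg method over these genes, and an adjusted value under 0.05 counted as a call. The 13 contrasts were each later time against 0 h within each arm, EGF+LA3IK against EGF at each time, and the difference between arms in the change from 0 h. Levels are counts per M (CPM) on the TMM-scaled library size.

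The following were fixed before the data were examined: the groups, these contrasts and tests, the alternatives except those named as later, 23 gene lists, and the rule for which genes are named. The lists covered immediate early factors, ERK and EGFR feedback inhibitors, ERBB receptors and ligands, NF-kB targets, matrix proteases, integrins and laminins, epithelial and mesenchymal state, the actin cytoskeleton, MIEN1 with its chromosomal neighbours, G1/S genes, G2/M genes, FOXO-associated genes, cholesterol synthesis, the integrated stress response, heat shock, NRF2 and metal response, hypoxia and glycolysis, interferon-stimulated genes, apoptosis and p53, ribosomal proteins, mitochondrially encoded genes, histone genes without poly(A) tails, and markers of other cell types. Named genes were the 8 largest increases and 8 largest decreases that passed, with a mean of at least 1 log2 CPM and no overlap of CPM between the 2 groups. For the course with both agents and for the differences between arms it was 5 each way, the latter without the overlap condition. Up to 4 members per described list with the smallest p were added, as was a fixed panel that included MIEN1, EGFR, ERBB2, FOS, EGR1, DUSP6, HBEGF, MYC, PLAUR, VEGFA and CXCL8. Where nothing passed, the 5 smallest p-values were named as not passing. Some genes that met this rule are left out of the text. Genes outside this rule are marked as chosen after their values were seen.

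Lists were tested against all other genes with camera at an inter-gene correlation of 0.01, again with the correlation estimated from the data, and with fry, which asks whether a list moves on balance in 1 direction. P-values for lists were adjusted over the lists of a comparison. Response size was the median difference between arms over genes that passed and changed at least 2-fold in the average of both arms, tested with fry on the difference contrast. Per-library mean response was compared by an exact two-sided permutation test, whose smallest p for 3 against 3 is 0.1. The library with LA3IK alone entered no test. Its lists were set against 10000 random lists of the same size matched on mean level.

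Alternatives were DESeq2 size factors, DESeq2 1.42.0 Wald tests, no low-count filter, summing per symbol, a replicate block, fits on the compared groups alone, another prior count, other choices of response genes, and leaving out each library in turn. Chosen after seeing the data were a correction for GC content, fitted per library by loess with span 0.3 and entered as offsets, the same with transcript length, the same with the replicate block, and a fit without the 6 h groups.

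The tests were also tried on simulated data, the GC trend only after such a trend had been seen. In the 1 h against 0 h comparison of EGF, with known changes drawn into the counts, edgeR recovered 44 of 67 genes changed 1.5-fold, 58 of 67 changed 2-fold and 65 of 66 changed 4-fold, and called 6 of 18197 unchanged genes. DESeq2 recovered 48, 57 and 65 and called 21 unchanged genes. Under a simulated GC trend in the 6 h comparison of arms, 12104 unchanged genes were called without the correction and 5 with it. The simulated trend followed the same GC value per gene that the correction uses. A raised list was found and 0 of 22 unchanged lists were called by each of the 3 list tests. Genes were drawn independently of each other, so the list tests were not tried under correlation between genes. Equal simulated responses at 1 h gave a median difference of 0.016 and a simulated weaker response with the peptide gave -0.98.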

Results

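Messenger RNA was measured in serum-starved PC3 prostate cancer cells over a time course of EGF, with and without LA3IK, a peptide based on MIEN1. MIEN1 (migration and invasion enhancer 1) is a small membrane-associated protein whose gene lies beside ERBB2. The labels state the question as how the peptide alters gene expression over time in cells stimulated with EGF. In each arm, cells were sampled at 0 h, 30 min, 1 h and 6 h with 3 libraries per group, and 1 further library received the peptide without EGF for 6 h. Libraries held between 13.8 and 41.4 M counts. Each value below is a mean CPM ± SD (n = 3) or a log2 fold change ± its standard error from edgeR's quasi-likelihood fit of 24 libraries, in which 18397 genes were tested. Genes described as having risen or fallen passed that test after Benjamini-Hochberg adjustment.

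MIEN1 itself (ENSG00000141741.11, chromosome 17, 39728496 to 39730532 on hg38, minus strand) was at 18.1 ± 0.987 CPM before EGF and at 15.6 ± 2.40, 19.8 ± 0.333 and 20.1 ± 1.43 CPM at 30 min, 1 h and 6 h. With EGF and LA3IK its levels were 16.5 ± 0.270, 18.2 ± 0.179, 17.7 ± 0.603 and 17.8 ± 1.32 CPM in the same order. None of these differences in MIEN1 passed, by time or between arms at a matched time. The smallest adjusted p among those comparisons, 0.12, came from the arms at 6 h (edgeR quasi-likelihood test, Benjamini-Hochberg). MIEN1 overlaps ERBB2 on the opposite strand, so its count is uncertain.

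**Figure D1:**
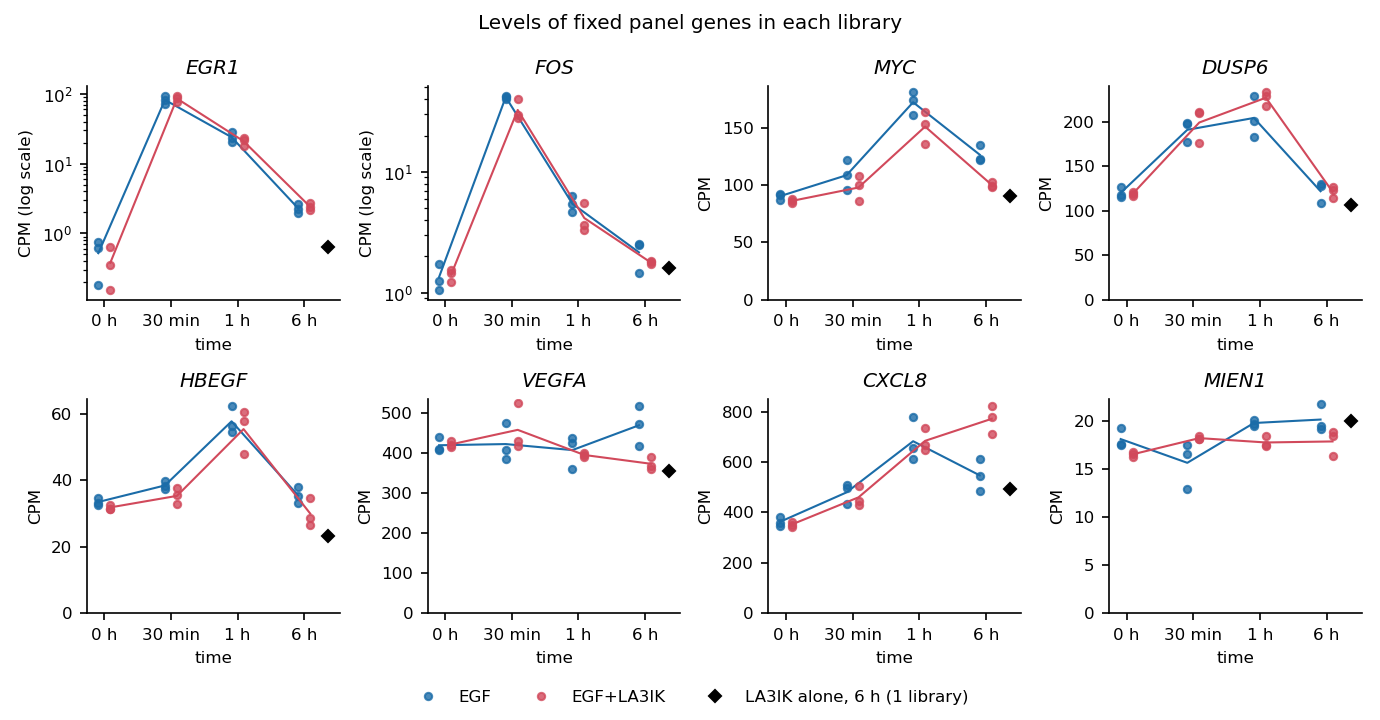
Levels of 8 fixed panel genes in CPM at 0 h, 30 min, 1 h and 6 h, with 1 point per library, lines through the group means, and a diamond for the single library given LA3IK alone. EGR1 and FOS are on log axes and peak at 30 min in both arms, while no difference in MIEN1 passed.

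The first comparison asked which genes differed from 0 h after 30 min of EGF, and 72 genes were higher and 24 lower. No group at a later time went without both agents. In this and the later comparisons with 0 h, an effect of EGF therefore cannot be told apart from time in culture. EGR1, an early growth response transcription factor (chromosome 5, 138465479 to 138469303), rose 152-fold, from 0.520 ± 0.299 to 82.1 ± 11.1 CPM (log2 7.25 ± 0.24, adjusted p = 1.6e-14 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). FOS, a subunit of the AP-1 transcription factor, rose 31.1-fold to 41.6 ± 1.39 CPM (log2 4.96 ± 0.21). KLF2, EGR2 and NR4A1, further transcription factors, rose 6.68-, 4.95- and 3.74-fold, and CCN2, a secreted matrix-associated protein, rose 3.53-fold. FOSB rose 12.2-fold, although it overlaps ERCC1 on the opposite strand and is uncertain. MT-TF, a mitochondrial transfer RNA, rose 3.47-fold to 5.52 ± 1.37 CPM.

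The 8 largest decreases at 30 min were mainly noncoding transcripts. ZNF436-AS1 fell by 1.54 ± 0.19 on the log2 scale, to 2.13 ± 0.310 CPM, and is uncertain because it lies antisense to ZNF436. CAPN10-DT, MRPL20-DT and RNF139-DT, transcripts divergent from coding genes, fell by 0.89, 0.87 and 0.69. The microRNA host transcript MIR3142HG fell by 0.80. C10orf95-AS1 and TMED2-DT, which overlap genes on the opposite strand, fell by 0.69 and 0.67. The only coding gene of the 8 was CLK1, a kinase of splicing factors, which fell by 0.62 ± 0.11 to 60.6 ± 5.30 CPM.

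Among the gene lists, 19 of 35 immediate early factors rose and 0 fell (25 adjusted over the list alone). JUN rose 2.78-fold and ATF3 2.82-fold. Of 28 ERK and EGFR feedback inhibitors, 10 rose (12 adjusted over the list alone), including the phosphatases DUSP1 (2.81-fold) and DUSP6 (1.59-fold, to 191 ± 12.1 CPM), SPRY1 (1.82-fold) and TRIB1 (1.80-fold). In the NF-kB list, 3 of 34 rose (10 adjusted over the list alone). They were NFKBIZ (2.32-fold, uncertain because it overlaps NXPE3) and the chemokines CXCL2 (1.78-fold) and CXCL8 (1.32-fold). All 3 lists passed camera, with adjusted p = 9.9e-10, 1.4e-07 and 0.0050 with an estimated correlation. ADAMTS1, a matrix protease, rose 1.77-fold. PPP1R15A rose 1.40-fold and GDF15, a stress-induced cytokine whose gene holds MIR3189, 1.39-fold, while DDIT4, an inhibitor of mTORC1 signalling, fell by 0.48 ± 0.09. HBEGF did not pass, at 38.5 ± 1.14 CPM against 33.5 ± 1.18.

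As technical signs, 2 of 17 histone genes without poly(A) tails were higher (5 adjusted over the list alone), H1-4 among them at 1.67 ± 0.537 against 0.719 ± 0.102 CPM, and the list kept its call with adjusted p = 0.0019 with an estimated correlation. The mitochondrial list had 2 of 15 genes higher, MT-RNR2 by 1.45-fold, and lost its call (adjusted p = 0.25 with an estimated correlation). Without replicate 1 of EGF 0 h, 59 genes passed in place of 96, and a fit on the 2 groups alone gave 162. CXCL8 (log2 0.25), TMED2-DT (-0.63) and MT-RNR2 (0.53) lost their calls after correction for GC content. With GC and length correction CXCL8 again did not pass (0.30), while TMED2-DT (-0.67) and MT-RNR2 (0.54) did.

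By 1 h of EGF, 331 genes were higher and 128 lower. EGR1 stood at 24.0 ± 3.86 CPM (log2 5.46 ± 0.25 against 0 h) and FOS 4.12-fold at 5.45 ± 0.837 CPM, both below their 30 min levels. KLF2, EGR2 and NR4A1 stood 5.96-, 4.03- and 4.62-fold above 0 h, and FOSB, uncertain as above, 16.3-fold. CCN2 rose 5.65-fold to 115 ± 37.2 CPM and ATF3, a stress-induced repressor, 4.27-fold (log2 2.09 ± 0.09). MYC, a driver of growth programmes, rose 1.91-fold (log2 0.93 ± 0.08), and CXCL8 (interleukin 8) rose 1.88-fold to 683 ± 86.7 CPM. SLC30A1, a zinc exporter, rose 3.39-fold to 50.6 ± 8.87 CPM.

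The largest decreases at 1 h were LINC01355, a noncoding RNA, which fell by 1.17 ± 0.23, and DDIT4, which fell by 1.10 ± 0.09 to 94.6 ± 13.4 CPM. HOXB4, which overlaps HOXB3 and is uncertain, fell by 1.02, and the sphingosine-1-phosphate receptor gene S1PR5 fell by 0.96. SLC16A4-AS1, ZNF436-AS1, SPACA6 and SLC23A3 fell by 0.97, 0.92, 0.79 and 0.79, each overlapping another gene and therefore uncertain. CDKN1B, a cyclin-dependent kinase inhibitor, and CCNG2, both of the FOXO-associated list, fell by 0.77 ± 0.08 and 0.40 ± 0.08. They were the 2 of 21 members that passed (3 lower and 1 higher adjusted over the list alone), and the list's call was lost (adjusted p = 0.32 with an estimated correlation).

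At 1 h, 25 of 35 immediate early factors were higher (29 higher and 1 lower adjusted over the list alone), JUN 2.75-fold and MCL1, an anti-apoptotic gene that overlaps others, 1.95-fold. Feedback inhibitors were higher for 12 of 28 (14 adjusted over the list alone), among them SOCS3 (2.54-fold), DUSP5 (2.41-fold) and TRIB1 (2.09-fold). NF-kB targets rose for 13 of 34 (16 higher and 1 lower adjusted over the list alone), with TNFAIP3 2.30-fold, NFKBIA 1.76-fold and NFKBIZ 2.46-fold. The EGFR ligand genes HBEGF (1.73-fold) and AREG (1.62-fold) were the 2 of 13 ERBB genes that rose (2 adjusted over the list alone). Matrix protease genes rose for 4 of 22 (5 adjusted over the list alone), including ADAMTS1 (2.77-fold) and PLAU, encoding urokinase (1.27-fold to 1500.2 ± 59.7 CPM). These 5 lists kept their camera calls, with adjusted p between 8.8e-09 and 0.042 with an estimated correlation.

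Smaller groups followed at 1 h. SNAI2, a transcription factor of mesenchymal state, rose 2.19-fold. In the actin list 5 of 49 rose (9 adjusted over the list alone; adjusted p = 0.042 with an estimated correlation). In the stress response list, 8 of 28 rose and 1 fell (10 and 1 adjusted over the list alone; adjusted p = 0.043 with an estimated correlation), with PPP1R15A 1.78-fold and CHAC1 1.78-fold. The chaperone gene DNAJB1 rose 1.47-fold, the metallothionein gene MT1X 1.62-fold, GADD45B 1.82-fold and CDKN1A 1.51-fold. MT1X belongs to a family of near-identical genes and is uncertain. Mitochondrially encoded genes were higher for 11 of 15 (15 adjusted over the list alone), MT-ND1 by 1.44-fold, and took 6.16 ± 0.0881% of counts against 5.07 ± 0.0484% at 0 h. Histone genes without poly(A) tails were higher for 5 of 17 (9 adjusted over the list alone), H2AC6 by 1.29-fold. GC correction moved the count from 459 to 690, and a fit on the 2 groups alone gave 481 genes higher and 427 lower.

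**Figure D2:**
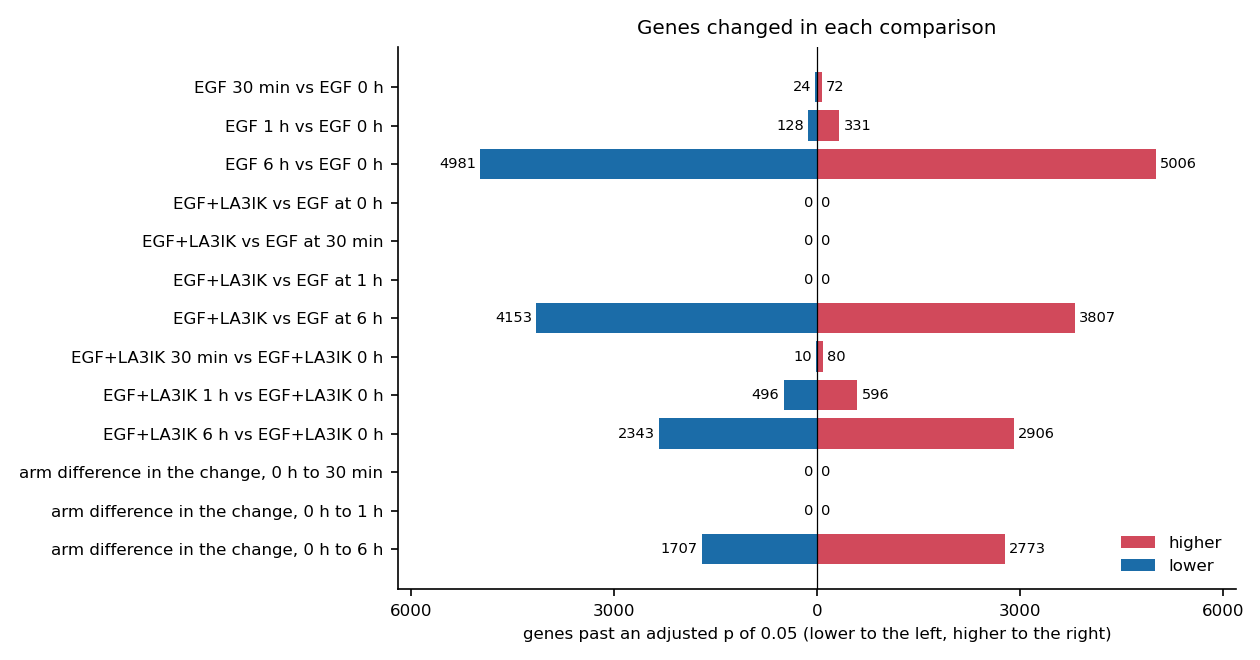
Bars give, for each of the 13 comparisons, how many of 18397 genes were lower (left) or higher (right) past an adjusted p of 0.05 by edgeR's quasi-likelihood test. Counts were 0 between the arms at 0 h, 30 min and 1 h and 7960 at 6 h. In a separate fit with GC correction, 4825 of the 18397 genes passed at 6 h.

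After 6 h of EGF, 5006 genes were higher and 4981 lower. The largest increases included the keratin gene KRT75 (4.16-fold to 23.4 ± 4.21 CPM), the collagenase gene MMP1 (3.48-fold to 18.1 ± 0.251 CPM, log2 1.80 ± 0.12), the cadherin gene CDH6 (3.28-fold) and TGFBI (3.26-fold). EGR1 remained 4.21-fold above 0 h at 2.29 ± 0.325 CPM. DIO3, encoding a thyroid hormone deiodinase, rose 3.23-fold, and PMF1-BGLAP and TEN1 rose 4.05- and 3.19-fold, all 3 overlapping other genes and uncertain. The largest decreases were ZBTB20, which fell by 3.24 ± 0.87, and KIAA0408, which fell by 2.98 ± 0.73 to 0.436 ± 0.443 CPM, both at overlapping loci. LINC00504 fell by 2.67, the pseudogenes ZNF204P, TLK2P2 and KLRA1P by 2.45, 2.43 and 2.30, the RNA-binding protein gene RBMS3 by 2.30 and the ciliary transport gene IFT80 by 2.24.

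Genes low in GC content were lower in these libraries. Across 12014 protein-coding genes the change from 0 h to 6 h of EGF had a Spearman rho of 0.50 with GC content. Genes are not independent replicates here. The median log2 level of the genes in the lowest-GC group of 5 was -0.80 ± 0.086 in the 3 libraries, against -0.025 ± 0.0099 at 0 h. Of the genes with large decreases, RBMS3 stood at -1.30, IFT80 at -1.16, KLRA1P at -1.36, ZNF204P at -1.76, TLK2P2 at -2.36 and LINC00504 at -2.13 after GC correction. ZBTB20 (-2.71) and KIAA0408 (-2.04) kept their calls with it and lost them with GC and length correction (-1.43 and -1.69).

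**Figure D3:**
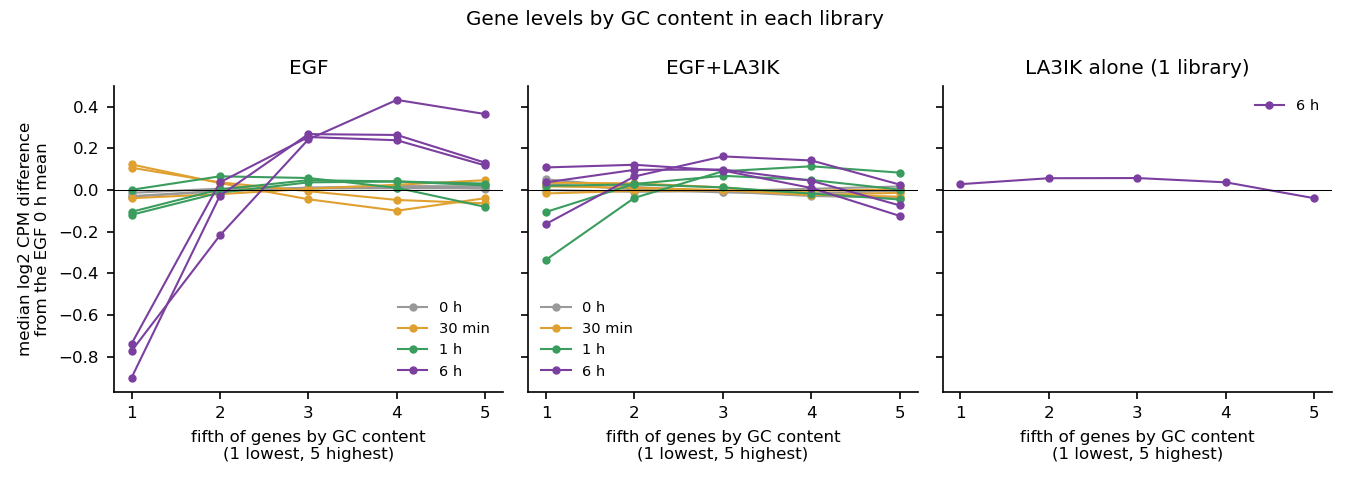
Median log2 CPM difference from the EGF 0 h mean for protein-coding genes in 5 groups of rising GC content, with 1 line per library and a panel per treatment. The 3 libraries of EGF 6 h lie between -0.90 and -0.74 in the lowest group, and the lowest value elsewhere is -0.34 in replicate 3 of EGF+LA3IK 1 h.

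At 6 h of EGF 20 of 25 cholesterol genes rose and 2 fell (21 and 2 adjusted over the list alone), SQLE, a monooxygenase of sterol synthesis, 1.87-fold. In the integrated stress response list 21 of 28 rose and 3 fell (21 and 5 adjusted over the list alone), with the serine synthesis gene PSAT1 1.67-fold and the amino acid transporter gene SLC7A5 2.09-fold. Heat shock genes rose for 11 and fell for 6 of 21 (11 and 6 adjusted over the list alone), with HSPA8 2.61-fold to 2299.7 ± 21.5 CPM and HSPA1A, which has a near-identical copy, 2.19-fold. In the NRF2 and metal list 16 of 24 rose and 1 fell (16 and 1 adjusted over the list alone), with the metallothionein genes MT1X 2.98-fold and MT2A 2.28-fold. Matrix protease genes rose for 17 and fell for 3 of 22 (17 and 3 adjusted over the list alone). These 5 camera calls were lost with adjusted p between 0.095 and 0.11 with an estimated correlation, and kept after GC correction.

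CCND1 (cyclin D1) rose 1.69-fold to 861 ± 31.6 CPM at 6 h, among 13 G1/S genes higher and 2 lower of 32 (13 and 2 adjusted over the list alone; adjusted p = 0.64 with an estimated correlation). The mitotic genes KIF11, HMMR and CDK1 fell by 1.80 ± 0.15, 1.67 ± 0.14 and 1.37 ± 0.12, and stood at -1.24, -0.67 and -0.25 after GC correction. In the G2/M list 8 of 28 were higher and 15 lower (9 and 15 adjusted over the list alone; adjusted p = 0.25 with an estimated correlation). ERBB genes fell for 6 and rose for 1 of 13 (6 and 1 adjusted over the list alone), with ERBB3 lower by 0.75 ± 0.09 and BTC, encoding betacellulin, by 1.24 ± 0.20 (-0.60 after GC correction). Among feedback inhibitors PHLDA2 rose 2.16-fold, and SPRED1 fell by 1.01 ± 0.09 but lost its call after GC correction and stood at 0.28 after GC and length correction. CXCL8 was 1.51-fold above 0 h (log2 0.59 ± 0.09, and 1.98 after GC correction).

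Of the remaining lists in the EGF arm at 6 h, 25 immediate early factors were higher and 1 lower, 16 and 4 feedback inhibitors, and 17 and 7 NF-kB targets (25 and 1, 16 and 4, 18 and 7 adjusted over the list alone). Their adjusted p = 0.11, 0.13 and 0.30 with an estimated correlation. Integrin and laminin genes were higher for 13 and lower for 9 of 26 (14 and 9 adjusted over the list alone), with ITGB6, an integrin chain, lower by 1.52 ± 0.16. Actin genes were higher for 29 and lower for 8 of 49 (29 and 8 adjusted over the list alone; adjusted p = 0.36 with an estimated correlation). Epithelial and mesenchymal state genes were 7 higher and 7 lower, FOXO-associated genes 6 and 9, hypoxia genes 14 and 5, apoptosis genes 12 and 6, and the MIEN1 list 3 and 1. Those counts were 7 and 7, 6 and 9, 14 and 5, 13 and 6, and 3 and 1 adjusted over the list alone, and none of these 5 lists passed camera. Interferon-stimulated genes were 2 higher and 7 lower of 25 (2 and 7 adjusted over the list alone), with IFI44L lower by 1.91 ± 0.13 (-1.11 after GC correction).

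Ribosomal protein genes rose for 45 of 46 (45 adjusted over the list alone), RPS6 by 1.31-fold, with adjusted p = 0.36 with an estimated correlation. Mitochondrially encoded genes rose for 15 of 15 (15 adjusted over the list alone; adjusted p = 0.18 with an estimated correlation), MT-CO1 by 1.42-fold, and took 6.49 ± 0.102% of counts. Histone genes without poly(A) tails were 8 higher and 1 lower of 17 (8 and 1 adjusted over the list alone; adjusted p = 0.12 with an estimated correlation). Markers of other cell types were 1 higher and 2 lower of 14, and did not pass camera.

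At 0 h the arms were compared for a starting difference, although the labels do not state how long these cells had met the peptide, and 0 genes passed in edgeR's quasi-likelihood test. At an unadjusted p under 0.05 there were 419 genes, fewer than the 0.05 share of 18397 tested genes that chance alone would give. Such a shortfall does not show that the arms were alike, since the fit pooled the spread of all groups. Between replicates, the chi-square per degree of freedom was 2.99 to 4.05 at 0 h and reached 24.5 at EGF 6 h. DESeq2 called 3, and a fit on these 6 libraries alone called 232 higher and 83 lower. The 5 smallest p-values, none passing, belonged to DCLK2 (5.56 ± 0.324 with the peptide against 3.92 ± 0.202 CPM), LINC00622 (0.299 against 0.785), BUB1B-PAK6 (0.0292 against 2.30), ZSWIM8-AS1 (1.41 against 0.395) and PRRG2 (4.58 against 2.89). The last 3 overlap other genes and are uncertain. Ribosomal protein genes had a median of -0.11 with 0 members passing, and a camera call lost with adjusted p = 0.82 with an estimated correlation.

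At 30 min the arms again differed in 0 genes by edgeR, 1 by DESeq2 and 4 in a fit on the 6 libraries alone. At an unadjusted p under 0.05 there were 573 genes, again fewer than chance alone would give, with the limit stated for 0 h. The smallest p-values, none passing, were for LYRM4-AS1 (0.962 with the peptide against 1.94 CPM, antisense to RPP40), ALPP (0.228 against 0), CELF5 (2.27 against 1.07), UBE2R2 (82.0 against 69.6) and GPR75 (1.48 against 2.46, overlapping ASB3). FOSB stood at 20.2 ± 5.26 against 37.5 ± 12.5 CPM and ATF3 at 56.9 against 69.0 CPM (log2 -0.28 ± 0.08), neither passing. The immediate early list had 0 members passing (1 lower adjusted over the list alone) and a camera call lost with adjusted p = 0.69 with an estimated correlation. The same held for interferon-stimulated genes (median 0.10, adjusted p = 0.73 with an estimated correlation).

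At 1 h, 0 genes passed between the arms by edgeR, and 8 were called by DESeq2, all lower with the peptide. There were 831 at an unadjusted p under 0.05, again fewer than chance alone would give, with the limit stated for 0 h. The 5 smallest p-values included 4 EGF-responsive genes, each at a lower level with the peptide. ATF3 was at 74.4 ± 4.83 CPM with the peptide, 1.40-fold below its level without it (log2 -0.49 ± 0.08, adjusted p = 0.060 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). SOCS3 was at 66.2 ± 11.2 against 92.9 ± 7.77 CPM (log2 -0.49 ± 0.10), TRIB1 at 211 ± 15.7 against 275 ± 22.2 (log2 -0.38 ± 0.08) and FOSB at 22.4 ± 3.88 against 50.2 ± 8.59 (log2 -1.17 ± 0.22). TUB, the fifth, had a difference of -1.59 ± 0.28 from 4.54 ± 0.109 CPM. EGR1 had a difference of -0.18 ± 0.16 from 24.0 ± 3.86 CPM, FOS at 4.14 ± 1.17 against 5.45 ± 0.837, and DUSP6 at 227 ± 8.14 against 205 ± 23.0.

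As a list, 35 immediate early factors had a median of -0.15 at 1 h, with 6 lower adjusted over the list alone and 0 over all genes. The camera call was lost with adjusted p = 0.072 with an estimated correlation, and fry gave 0.059. KLF2 (log2 -0.71 ± 0.18) and CSRNP1 (log2 -0.47 ± 0.11) were among its members with the smallest p. Feedback inhibitors had a median of -0.07, with 3 lower adjusted over the list alone and 0 over all genes, adjusted p = 0.072 with an estimated correlation and 0.035 by fry, DUSP1 standing at -0.41. Interferon-stimulated genes had a median of 0.16 with 0 passing, and adjusted p = 0.39 with an estimated correlation. GC correction gave 1 gene higher and 8 lower, ATF3, SOCS3, TRIB1, CSRNP1 and TUB among them, and leaving out replicate 2 of EGF 1 h also gave 8.

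At 6 h, 3807 genes were higher and 4153 lower with EGF and LA3IK than with EGF alone, of which 1476 and 55 differed at least 2-fold. SLC30A1, the zinc exporter (chromosome 1, 211571568 to 211579161), stood 3.77-fold higher, at 55.0 ± 7.51 against 14.6 ± 3.23 CPM (log2 1.92 ± 0.19, and 1.52 after GC correction). The largest increase was KIAA0408 (8.96-fold, uncertain because of an overlapping gene), followed by LRRCC1, a centrosomal protein gene (5.35-fold), SAMD9L, an interferon-inducible gene (4.42-fold), FAM111B (3.97-fold), the cohesin acetyltransferase gene ESCO2 (3.96-fold, with genes overlapping on the other strand), SPX (3.95-fold), DOCK11 (3.95-fold) and the ciliary gene LCA5 (3.94-fold). Each of these 8 stayed higher after GC correction, between 1.03 and 2.24 on the log2 scale. Lower with the peptide were TEN1 (by 1.25 ± 0.46), ANGPTL2 (by 1.21 ± 0.20), CYTH4 (by 1.12 ± 0.22), the focal adhesion gene TNS4 (by 1.10 ± 0.13, to 36.4 ± 4.07 CPM), ARNT2 (by 1.04 ± 0.21), NTN5 (by 1.01 ± 0.24), CHST6 (by 0.99 ± 0.21) and POU2F2-AS2 (by 0.95 ± 0.24). TEN1, ANGPTL2 and POU2F2-AS2 overlap other genes and are uncertain, and TEN1 lost its call after GC correction.

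Mitotic genes were higher with the peptide at 6 h for 15 of 28 and lower for 6 (15 and 6 adjusted over the list alone). CDK1 was at 93.7 ± 12.7 against 37.0 ± 7.04 CPM (log2 1.34 ± 0.12, and 0.25 after GC correction), KIF11 at 31.9 ± 6.46 against 10.2 ± 1.79 (log2 1.64 ± 0.15) and HMMR at 26.3 against 9.43. HSP90AA1, a chaperone gene, was 1.80-fold higher. Immediate early factors were lower for 13 of 35 (13 adjusted over the list alone), IER3 by 0.50 ± 0.08, FOSL1 by 0.49 ± 0.08 and SRF by 0.41 ± 0.08. Hypoxia and glycolysis genes were lower for 20 and higher for 3 of 27 (20 and 3 adjusted over the list alone), the glucose transporter gene SLC2A1 by 0.48 ± 0.09 and LDHA by 0.26 ± 0.05. Ribosomal protein genes were lower for 43 of 46 (44 adjusted over the list alone), RPL11 by 0.29 ± 0.06, and actin genes lower for 29 and higher for 10 of 49 (29 and 10 adjusted over the list alone). Mitochondrially encoded genes were lower for 14 of 15 (14 adjusted over the list alone), MT-CO1 by 0.40 ± 0.06. After GC correction HSP90AA1 stood at 0.55, IER3 at -0.27, FOSL1 at -0.25, SRF at -0.17, SLC2A1 at -0.27, LDHA at -0.52 and RPL11 at -0.17. None of the camera calls at this time held, with adjusted p = 0.62 for each of these 6 lists with an estimated correlation.

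Of the fixed panel, MYC was lower with the peptide at 6 h by 0.34 ± 0.08, VEGFA by 0.33 ± 0.09 and HBEGF by 0.24 ± 0.09, of which MYC kept its call after GC correction (-0.21) and the others lost it. PLAUR fell by 0.21 ± 0.07 and stood at 0.01 after GC correction, and ERBB2 did not pass (-0.08 ± 0.06) and stood at 0.15 after it. CXCL8 (chromosome 4, 73740519 to 73743716) was higher by 0.50 ± 0.09, at 772 ± 57.0 against 548 ± 64.7 CPM, and turned to -0.78 after GC correction. SPRED1 was higher by 0.83 ± 0.09 and turned to -0.17. Across 12014 protein-coding genes, the difference between arms at 6 h had a Spearman rho of -0.74 with GC content, where genes are not independent replicates. GC correction gave 2270 genes higher and 2555 lower, GC and length correction 1831 and 3475, and a fit on the 6 libraries alone 3254 and 1769.

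**Figure D4:**
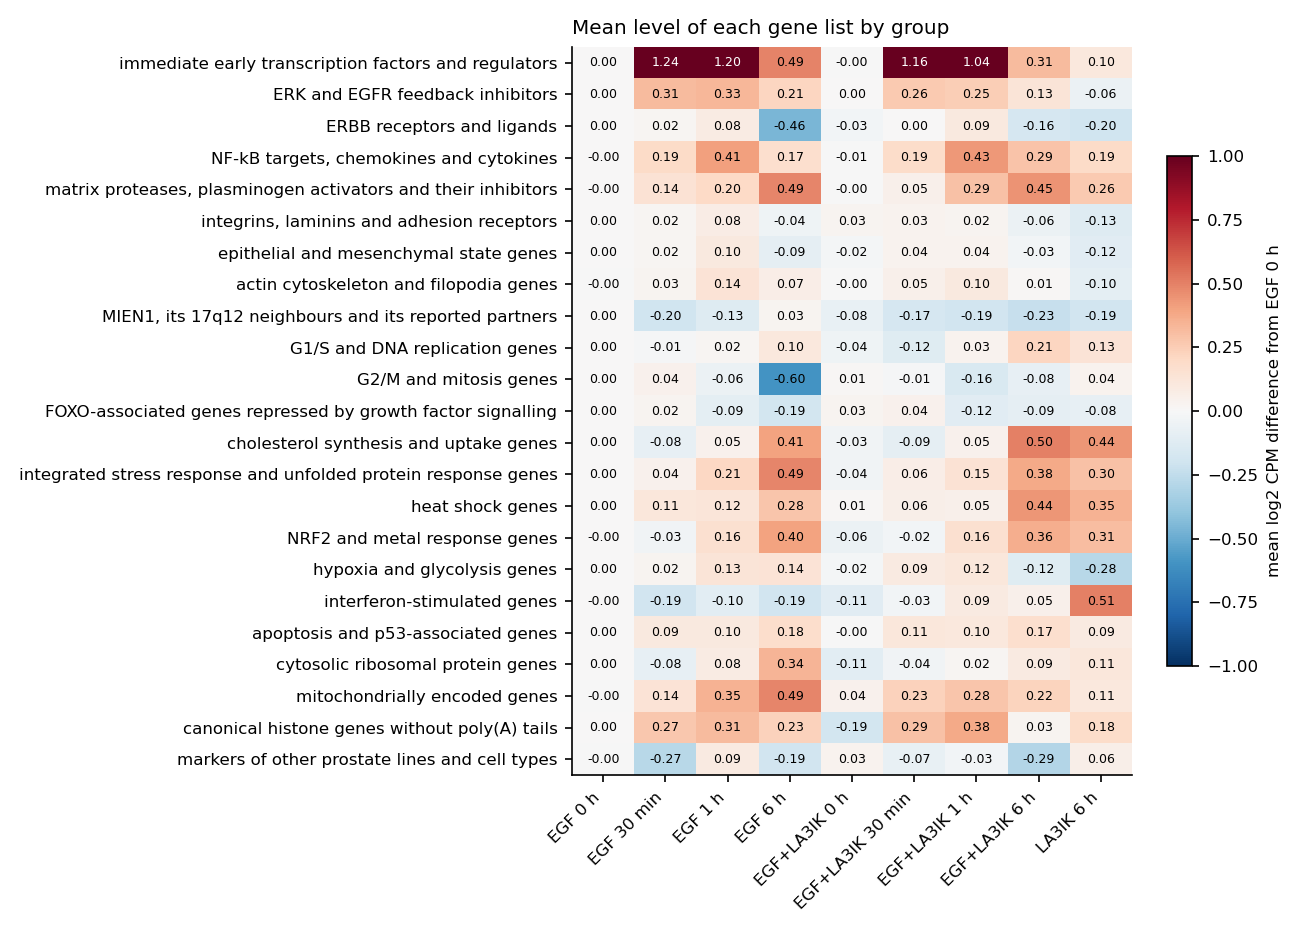
Mean log2 CPM difference of each of the 23 gene lists from its level at EGF 0 h, by group, with the single library given LA3IK alone in the last column. Immediate early factors stand highest at 30 min and 1 h in both arms, and the cholesterol, stress response and heat shock lists stand above 0 h in all 3 columns at 6 h.

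Within the arm that received both EGF and LA3IK, the course was compared with its own 0 h group. At 30 min 80 genes rose and 10 fell, and 58 of the 80 also rose with EGF alone, where 0.313 shared genes would come from independent lists. EGR1 rose 230.1-fold, from 0.379 ± 0.240 to 85.8 ± 9.55 CPM (log2 7.85 ± 0.26), a fold change that rests on a very low 0 h level. FOS rose 23.0-fold, FOSB 7.24-fold, KLF2 5.30-fold, EGR2 4.41-fold and DUSP6 1.68-fold. ZNF436-AS1 fell by 1.04 ± 0.17, CLK1 by 0.73 ± 0.11, MRPL20-DT by 0.65, MIR3142HG by 0.65 and RNF139-DT by 0.60. Immediate early factors rose for 19 of 35 (26 adjusted over the list alone) and feedback inhibitors for 8 of 28 (11 higher and 1 lower adjusted over the list alone), with adjusted p = 6.4e-10 and 1.3e-06 with an estimated correlation. A fit on the 2 groups alone called 147 genes higher and 73 lower.

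At 1 h in that arm 596 genes rose and 496 fell, and 248 of the rising and 73 of the falling genes were shared with EGF alone, against 10.7 and 3.45 from independent lists. EGR1 stood 56.3-fold above 0 h, FOSB 8.05-fold, CCN2 5.82-fold, EGR2 3.53-fold, DUSP6 1.91-fold and SLC30A1 4.37-fold, at 60.3 ± 18.2 CPM. LINC01355 fell by 1.51 ± 0.24, PCMTD1 by 1.27 ± 0.27, HMGN5, a nucleosome-binding protein gene, by 1.10 and PDK4, a brake on pyruvate oxidation, by 1.07 ± 0.14. GUSBP11, an overlapping pseudogene, fell by 1.25. Immediate early factors rose for 23 of 35 (25 higher and 1 lower adjusted over the list alone) and NF-kB targets for 15 of 34 (19 and 1 adjusted over the list alone), both calls kept with an estimated correlation. As a technical sign, mitochondrially encoded genes took 6.03 ± 0.251% of counts against 5.26 ± 0.0305% at 0 h. The total of 1092 moved to 2437 without replicate 2 of EGF+LA3IK 1 h and to 436 without replicate 3, and GC correction gave 1758.

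At 6 h with both agents 2906 genes rose and 2343 fell, and 2300 of the rising and 1588 of the falling genes were shared with EGF alone, against 790.8 and 634 from independent lists. EGR1 stood 6.47-fold above 0 h, SLC30A1 3.98-fold, the metallothionein genes MT1F and MT1X 3.88- and 3.87-fold, and MMP1 3.02-fold. GIPR, a gut hormone receptor gene, fell by 1.92 ± 0.31, LMNTD2-AS1 by 1.85, ADGRB1 by 1.72, HSF4 by 1.67 and TNFRSF6B by 3.27 ± 1.18, where LMNTD2-AS1, HSF4 and TNFRSF6B overlap other genes and are uncertain. Cholesterol genes rose for 24 of 25 (24 adjusted over the list alone), SQLE 1.78-fold. Heat shock genes rose for 14 of 21 (14 adjusted over the list alone), HSPA8 2.47-fold, and stress response genes for 18 of 28 with 1 lower (20 and 1 adjusted over the list alone), ASNS, encoding asparagine synthetase, 2.01-fold. NRF2 and metal genes rose for 14 of 24 with 1 lower (14 and 1 adjusted over the list alone). These 4 lists held in camera, with adjusted p = 0.0012, 0.00084, 0.029 and 0.012 with an estimated correlation. CXCL8 rose 2.19-fold to 772 ± 57.0 CPM and IL6, with antisense partners, 2.58-fold.

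The last comparisons tested whether the change from 0 h itself differed between arms. From 0 h to 30 min 0 genes passed by edgeR, with 547 at an unadjusted p under 0.05, 3 by DESeq2 and 61 in a fit on the 4 groups alone. The smallest p-values, none passing, were for DCLK2, SNRPA1P1, H2BC21, CWC15 and RPUSD2, with differences of -0.74 ± 0.18, 1.24 ± 0.31, 0.39 ± 0.11, 0.32 ± 0.09 and 0.49 ± 0.14. From 0 h to 1 h 0 genes passed by edgeR, with 691 at an unadjusted p under 0.05, and ATF3 was among the 5 smallest p-values (difference -0.51 ± 0.12), with ZSWIM8-AS1 (-3.06), DCLK2 (-0.72), IRGQ (0.40) and BUB1B-PAK6 (9.98). The counts of 547 and 691 were each fewer than chance alone would give, which does not show that the changes were equal. Of immediate early factors, 2 were lower adjusted over the list alone, and the camera call was lost (adjusted p = 0.39 with an estimated correlation).

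From 0 h to 6 h the change differed between arms for 2773 genes in the upward and 1707 in the downward direction. SLC30A1 went from 15.0 ± 1.49 to 14.6 ± 3.23 CPM with EGF and from 13.8 ± 0.508 to 55.0 ± 7.51 with both agents, a difference of 2.03 ± 0.28 (1.65 after GC correction). CDK1 went from 95.7 ± 1.03 to 37.0 ± 7.04 CPM and from 93.9 ± 5.16 to 93.7 ± 12.7, a difference of 1.37 ± 0.16 (0.36 after GC correction). HSP90AA1, with WDR20 on the other strand, differed by 0.87 ± 0.11 and FOSL1 by -0.47 ± 0.11. The largest differences upward were KIAA0408 (3.23 ± 0.93), LRRCC1 (2.19 ± 0.30), MBNL3 (2.15 ± 0.32), RBMS3 (2.11 ± 0.37) and ESCO2 (2.04 ± 0.30). Downward they were TNFRSF6B (-5.83 ± 1.64), CHST6 (-1.23 ± 0.29), POU2F2-AS2 (-1.21 ± 0.34), ANGPTL2 (-1.21 ± 0.29) and ARNT2 (-1.20 ± 0.30). KIAA0408, MBNL3, RBMS3, ESCO2, TNFRSF6B, POU2F2-AS2 and ANGPTL2 share loci with other genes and are uncertain. After GC correction LRRCC1 stood at 1.11, MBNL3 at 1.30, RBMS3 at 1.18, ESCO2 at 1.24, HSP90AA1 at 0.59 and FOSL1 at -0.25, while KIAA0408 and POU2F2-AS2 lost their calls. GC correction gave 880 upward and 912 downward, and GC and length correction 702 and 1463.

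Response size was compared over genes that responded in the average of both arms. At 30 min 51 genes had a median difference of -0.11 with the peptide (fry p = 0.074, n = 12 libraries), and 191 genes with no fold minimum had -0.026. At 1 h 105 genes had 0.063 (fry p = 0.78, n = 12 libraries). Over 70 genes chosen from the EGF arm it was -0.26, but choosing genes by the libraries of 1 arm favours a weaker response in the other, so no p is given. At 6 h 1120 genes, 106 rising and 1014 falling, had a median difference of -0.90 (fry p = 0.00014, n = 12 libraries), -0.42 after GC correction and -0.24 over 10535 genes with no fold minimum. Per library, the mean signed response at 6 h was 1.57 ± 0.14 with EGF and 0.91 ± 0.16 with both agents, at an exact permutation p of 0.1, the smallest that 3 against 3 allows. It was 1.74 ± 0.022 against 1.60 ± 0.013 at 30 min and 1.33 ± 0.0075 against 1.45 ± 0.068 at 1 h, again at an exact permutation p of 0.1 each. These responses are changes from 0 h, so variation among the 0 h libraries enters neither the SD nor the permutation. Of 12 groupings that kept the later libraries in their real arms, 4 at 30 min, 7 at 1 h and 12 at 6 h gave as large a median difference in either direction, the real grouping included.

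**Figure D5:**
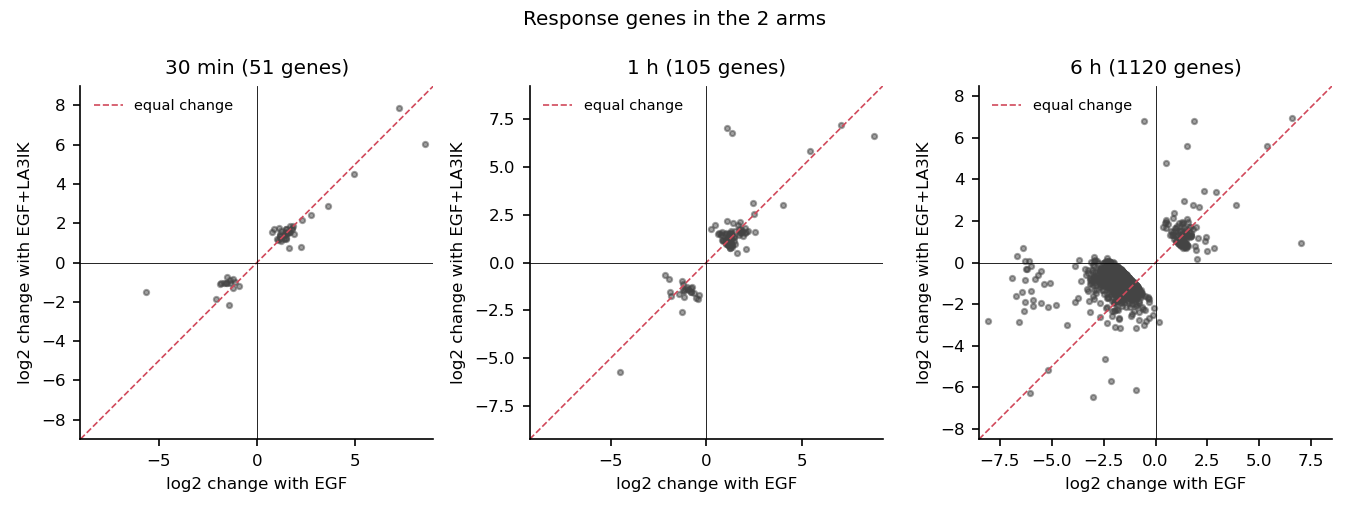
Log2 change from 0 h with EGF and LA3IK (vertical) against that with EGF (horizontal) for response genes, 1 point per gene, at 30 min (51 genes), 1 h (105) and 6 h (1120), with a dashed line at equal change. At 6 h most of the 1014 falling genes lie above the line, with a median difference over all 1120 genes of -0.90, or -0.42 after GC correction.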

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

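The GC correction of the 6 h calls, the comparison with the lowest library of other groups, the GC tests of the early and the 6 h lists, the test on the library without EGF, and the number of standard errors by which a value had to pass its bound were chosen only after the results were seen. The thinning of libraries, the noncoding transcripts, the course of the early genes and the regroupings of libraries were written down before their values were computed.

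The change from 0 h was set side by side in the 2 arms, and these values stood out because the arms differed. From 0 h to 30 min the interferon-stimulated list had a median difference of 0.20 and the ribosomal protein list 0.16 (adjusted p = 0.74 for each with an estimated correlation). From 0 h to 1 h the medians were -0.13 for immediate early factors, -0.10 for feedback inhibitors, 0.22 for interferon-stimulated genes and 0.051 for ribosomal protein genes. They were -0.069 for mitochondrially encoded genes and 0.18 for histone genes without poly(A) tails. The adjusted p = 0.39, 0.24, 0.39, 0.84, 0.78 and 0.21 with an estimated correlation, in that order.

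From 0 h to 6 h 4480 genes differed between arms in their change, and the size of the EGF response with LA3IK had a median difference of -0.90. The medians of lists were -0.24 for immediate early factors, -0.19 for actin genes, 0.34 for G2/M genes and -0.25 for hypoxia genes. They were 0.31 for interferon-stimulated genes, -0.15 for ribosomal protein genes and -0.29 for mitochondrially encoded genes. Their adjusted p = 0.71 for each of the 7 with an estimated correlation. Single genes with the largest differences were KIAA0408 (3.23), LRRCC1 (2.19), MBNL3 (2.15), RBMS3 (2.11), ESCO2 (2.04), TNFRSF6B (-5.83), CHST6 (-1.23), POU2F2-AS2 (-1.21), ANGPTL2 (-1.21) and ARNT2 (-1.20). After GC correction KIAA0408 and POU2F2-AS2 lost their calls.

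In the library with LA3IK alone, which entered no test, 5 lists lay at percentile 100 of random lists against the 0 h libraries of each arm. Their medians against EGF 0 h were 0.41 for cholesterol genes, 0.37 for the stress response, 0.29 for heat shock genes, 0.55 for interferon-stimulated genes and 0.40 for histone genes without poly(A) tails. Against EGF 0 h only, matrix proteases also lay at percentile 100 (median 0.25) and hypoxia genes at percentile 0 (-0.22). Against EGF+LA3IK 0 h only, metal response genes (0.26) and ribosomal protein genes (0.22) lay at percentile 100. This is 1 library without a replicate.

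Low-GC genes were lower in the 3 libraries of EGF 6 h, and 7960 genes differed between the arms at that time. A smooth trend on the GC value of each gene, as the whole cause of these calls, is argued against by the 4825 genes that passed after correction. In simulated libraries with such a trend 5 unchanged genes passed. The simulated trend followed the same GC value that the correction removes, so a bias that does not follow this value could still leave calls. Depth is argued against by the 7155 calls made after all libraries were thinned to the smallest total, of which 6934 were among the 7960. A GC bias arising in library preparation may still contribute. In the lowest-GC group, EGF+LA3IK minus EGF at 6 h had a median of 0.58 over noncoding and 0.82 over coding genes. The gap of -0.24 (standard error 0.078, n = 115) lay inside the range set beforehand by less than 1 standard error. The noncoding transcripts therefore do not decide the question. An effect of 6 h of EGF without the peptide on low-GC transcripts cannot be told apart from such a bias. The lowest library of another group stood at -0.34, and preparation batches were not given in the sources used here.

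Immediate early factors had a median of -0.15 with EGF and LA3IK against EGF at 1 h, but 0 of them passed over all genes and the list call was lost (adjusted p = 0.072 with an estimated correlation, 0.059 by fry), so the pattern itself is uncertain. GC content is argued against, but narrowly, by a list median of -0.16 (standard error 0.041, n = 35) after the correction. That median passed its bound by between 1 and 2 standard errors. Genes already falling from 30 min to 1 h had a median of -0.37 over 14 genes. That set holds the mitochondrial transfer RNAs MT-TV, MT-TT, MT-TF and MT-TP beside early genes such as FOS and EGR1. A response that runs earlier with the peptide could lower such falling genes but should raise those still rising. Those had a median of -0.11 (standard error 0.049, n = 41 genes), and 25 of the 41 were lower. The median passed the bound of -0.05 written beforehand by just over 1 standard error. Both standard errors are over genes measured in the same libraries, and such genes are not independent replicates. An earlier course is therefore left open, and the case against GC content rests on a list median that the correction did not reduce. That 1 standard error sufficed was settled only after the values were seen. Under the first reading, which asked for 2, both an earlier course and GC content would have stayed open.

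Heat shock, stress response, cholesterol and metal response lists had medians above 0 h at 6 h in both arms, but with EGF alone their calls were lost (adjusted p between 0.095 and 0.11 with an estimated correlation) and 6 of 21 heat shock genes fell. In the EGF arm, which carried the trend, GC content as the whole cause is argued against, but only narrowly. The smallest of the 4 list medians after correction was 0.38 (standard error 0.16). How many standard errors sufficed was settled only after the values were seen. Under the stricter first reading given above, GC content would have stayed open here too. The arm with the peptide carried no such trend, so its smallest corrected median of 0.23 decides nothing about GC content. A response that needs EGF could be set against the library with the peptide and no EGF, where the smallest of these medians was 0.23. That library is single and the peptide itself may raise these genes, so the need for EGF cannot be told apart from a response to time in culture or to the peptide.

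The libraries of each comparison of 2 groups were also regrouped in all 10 ways that keep 3 against 3, which are too few to exclude chance. For the EGF arm the real counts of 96, 459 and 9987 at 30 min, 1 h and 6 h were each reached in 1 of 10 ways, and the highest other counts were 0, 0 and 1. For the arm with both agents the counts of 90, 1092 and 5249 were each reached in 1 of 10, with 1, 0 and 0 as the highest others. Between arms the count of 0 at 0 h, 30 min and 1 h was reached in 10 of 10, which any grouping must do, so it tests nothing. The highest others were 0, 2 and 1. At 6 h 7960 was reached in 1 of 10, and the highest other was 1.

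For differences in change, the arms were regrouped within each time in 100 ways. Counts of 0 at 30 min and at 1 h were reached by 100 of 100, which any grouping must do, so these shares test nothing. The highest others were 2 and 1. The count of 4480 at 6 h was reached by 12 of 100, the highest other being 6122, so chance is not excluded by that share. All 12, the real grouping among them, kept the 6 h libraries in their real arms, and where the 6 h libraries were regrouped the highest count was 1. Response sizes of -0.11, 0.063 and -0.90 at 30 min, 1 h and 6 h were reached by 12, 45 and 12 of 100, with 0.19, 0.18 and 1.11 as the highest others, so chance is not excluded by those shares. At 6 h all 12 again kept the 6 h libraries in their real arms, and where these were regrouped the highest median was 0.66.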

How the results depend on the processing

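The GC correction, GC and length correction, the replicate block with GC correction and the fits without the 6 h groups were chosen only after the results were seen. With 3 libraries per group, 44 of 67 simulated 1.5-fold changes at 1 h were recovered, so others of that size can be missed. Thinned to the smallest total, the arms at 6 h differed in 7155 genes in place of 7960. The block by replicate number changed 0 of 245 gene values in direction and weakened 3. Replicate numbers carried no sign of pairing, since residuals of libraries with the same number had a median correlation of 0.003 over 84 pairs. The tests given above did not settle the cause of the GC trend.

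GC correction turned the direction of single genes. At 6 h of EGF, SPRED1 moved from -1.01 to 0.28 with GC and length correction. Between arms at 6 h, CXCL8 moved from 0.50 to -0.78 with GC correction, -0.48 with GC and length correction and -0.77 with the replicate block and GC correction. SPRED1 moved from 0.83 to -0.17, -0.37 and -0.17 in the same order. PLAUR moved from -0.21 to 0.010 with GC correction and 0.010 with the block added. ERBB2, which did not pass, moved from -0.08 to 0.15, 0.16 and 0.15.

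Counts of genes moved as follows. With GC correction EGF at 1 h gave 690 genes in place of 459, the arms gave 9 in place of 0 at 1 h and 4825 in place of 7960 at 6 h, the course with both agents gave 1758 in place of 1092 at 1 h, and the difference in change at 6 h gave 1792 in place of 4480. With GC and length correction those counts were 693 for EGF at 1 h, 7 and 5306 between arms at 1 h and 6 h, and 2165 for the difference in change. With the replicate block and GC correction they were 8 and 4789 between arms, 1886 for the course at 1 h and 1801 for the difference in change. In fits on the compared groups alone EGF gave 162 genes in place of 96 at 30 min and 908 in place of 459 at 1 h. Between arms such fits gave 315, 4 and 1 in place of 0 at 0 h, 30 min and 1 h, and 5023 in place of 7960 at 6 h. They gave 220 in place of 90 for the course at 30 min and 61 in place of 0 for the difference in change at 30 min. DESeq2 gave 3, 1 and 8 between arms at 0 h, 30 min and 1 h, 1856 for the course at 1 h and 3 for the difference in change at 30 min. Without the low-count filter, with counts summed per symbol, and without the 6 h groups, the arms differed in 1 gene each at 1 h in place of 0. Without the 6 h groups the course with both agents gave 1939 at 1 h.

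Response size at 30 min moved from -0.11 (fry p = 0.074, n = 12 libraries) to -0.21 with genes chosen from the EGF arm, to -0.10 with GC correction (fry p = 0.038, n = 12) and to -0.026 over 191 genes with no fold minimum (fry p = 0.49, n = 12). At 1 h it turned from 0.063 to -0.26 with genes from the EGF arm and to -0.027 without the low-count filter. Genes chosen from the EGF arm favour a weaker response in the other arm, so no p is given for them. At 6 h it moved from -0.90 to -0.24 over 10535 genes with no fold minimum and to -0.42 with GC correction. The share of genes in which the library with LA3IK alone lay nearer to the arm with the peptide moved from 93.4% to 88.2% over genes called with GC correction.

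Leaving out each library in turn gave these ranges. EGF gave 59 to 83 genes at 30 min, 307 to 386 at 1 h and 8912 to 9703 at 6 h. The arms differed in 0 genes at 0 h and 30 min, 0 to 8 at 1 h and 5929 to 8187 at 6 h. The course with both agents gave 63 to 71, 436 to 2437 and 4036 to 4559 at the 3 times. The difference in change gave 0, 0 to 1 and 3158 to 5490. Response size ran from -0.21 to -0.042 at 30 min, from -0.10 to 0.18 at 1 h, where 7 turned direction, and from -1.17 to -0.79 at 6 h. A count moved more than 1.5-fold without replicate 1 of EGF 0 h (59 for EGF at 30 min), without replicate 2 or 1 of EGF 1 h (8 and 1 between arms at 1 h), and without replicate 1 of EGF+LA3IK 0 h (1 for the difference in change at 1 h). The course at 1 h moved more than 1.5-fold without any of its libraries, to 497, 526 and 527 without replicates 1, 2 and 3 of 0 h and to 456, 2437 and 436 without those of 1 h.

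Of 245 gene values, GC correction left 225 the same, weakened 10, strengthened 6 and turned 4. Leaving out libraries left 1549 of 1614 the same, weakened 61 and strengthened 4. Of 126 list calls, an estimated correlation weakened 93, fry weakened 49 and GC correction 17.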

Other observations

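The values of single genes in the library with LA3IK alone were read without a test, and those outside the fixed panel were chosen only after they were seen.

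The library that received LA3IK without EGF for 6 h was set beside the 6 h groups. Of the 7960 genes that differed between the arms at 6 h, 7437 (93.4%) lay nearer to the group with both agents. These genes move together and this is 1 library, so the share carries no measure of variation between libraries. Low-GC genes were lower in the EGF 6 h libraries, so any library without that drop would tend to lie nearer to the other group. The 0 h libraries were not placed in this way, so the share does not single out an effect of the peptide. Over the 4825 genes called with GC correction it was 88.2%. SERPINB3, a serpin with the near-identical copy SERPINB4, was at 86.6 CPM in this library against 32.5 ± 0.657 with EGF and 81.2 ± 4.25 with both agents (n = 3), and was chosen after its values were seen. MYC was at 90.3 CPM against 127 ± 7.01 and 100.3 ± 2.33. VEGFA was at 357 against 470.4 ± 49.9 and 374 in the same order. In the lowest-GC group of genes its median log2 difference from 0 h was 0.03, against -0.80 ± 0.086 in the EGF 6 h libraries and -0.006 ± 0.14 with both agents.

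HSPA1A, with a near-identical copy, was at 147 CPM against 83.8 ± 0.764 at EGF 0 h, and MT1X at 45.3 against 14.4 ± 2.02, both chosen after their values were seen. MMP1, the collagenase, was at 10.8 CPM against 5.21 ± 0.179 at 0 h and 18.1 ± 0.251 after 6 h of EGF. CXCL8 was at 493 CPM, within the 485 to 614 of the EGF 6 h libraries, below the 772 ± 57.0 of both agents and above the 363 ± 19.1 of EGF 0 h. EGR1 was at 0.636 CPM, close to the 0.520 ± 0.299 of 0 h and below the 2.29 ± 0.325 and 2.41 ± 0.287 of the arms at 6 h. Interferon-stimulated genes had a median of 0.55 against EGF 0 h and hypoxia genes -0.22.

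Mitochondrially encoded genes took 6.49 ± 0.102% of counts after 6 h of EGF and 5.69 ± 0.339% with both agents, against 5.07 ± 0.0484% and 5.26 ± 0.0305% at 0 h. The library with the peptide alone stood at 5.45%. In low-GC genes the 6 h libraries with both agents ran from -0.16 to 0.11.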
